A study of Homo sapiens with 3 samples.

How the data were processed

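The study compared the abundance of tRNAs in MCF-10A cells, a non-tumorigenic line of human breast epithelial cells, after knockdown of eIF3e and after treatment with a control siRNA. eIF3e is a subunit of the translation initiation factor eIF3. Cells received 20 nM of siRNA for 72 h. Per the labels' protocols, 4 pmol of each of 4 synthetic tRNA standards of bacterial or yeast origin was added to 2 µg of total RNA, and a fluorescent oligonucleotide was ligated to the 3' ends of the tRNAs before hybridisation. The protocol describes both a charging and an abundance procedure, and it places periodate oxidation under abundance. Periodate destroys the 3' end of uncharged tRNA, so this step belongs, as background, to the measurement of charged tRNA, and the headings may have been exchanged. The design text names abundance, and the ratios are described here as abundance of tRNA that could be ligated. If periodate was used on these samples, they are ratios of charged tRNA instead. RNA from knockdown cells was labelled with Cy3 and RNA from control cells with Atto635 in all 3 ratios, and no ratio had the dyes swapped. The ratios come from 3 control cultures and 2 knockdown cultures, and ratios 1 and 2 share 1 knockdown RNA per the titles.

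The authors deposited scanner tables with the intensity of 800 spots per array in each channel, with local background, per the file headers. The tables held 41 human tRNA probes with 16 spots each, covering 20 amino acids and selenocysteine, and 4 probes for the standards with 24 spots each. Probe names give the amino acid and a number but no anticodon, so a probe is named here as the files name it (His1h, for example). The scanner table of ratio 2 was identical to that of ratio 1 in 56 of its 57 columns, and the remaining column, the background-subtracted Atto635 intensity, was the one used. Ratio 2 therefore shares the whole Cy3 measurement of ratio 1. A dye control array was also deposited. Which RNA it held in each channel is not given in the sources used here. The authors' series matrix holds a linear ratio per probe for 40 human probes, without Sec2h and the standard E.c. Lys-2. Set against the scanner values across 43 probes, these deposited ratios matched Cy3 over Atto635 divided by the dye control, with correlations of 0.993, 0.970 and 0.997 in log2, against 0.637, 0.807 and 0.637 without that division. Their medians were 0.985, 1.11 and 1.14. The direction and the division by the dye control were thus read from the values, and the authors' exact centring is not given in the sources used here.

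For the main estimates, background-subtracted mean intensities were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3. The log2 ratio of Cy3 over Atto635 was taken per spot, and a probe's value was the median of its unflagged spots. Each array was centred on the median of the 4 standards. The number of flagged spots was 24 in ratio 1, 46 in ratio 3 and 19 on the dye control. Ratio 2 repeats the flags of ratio 1 and has none of its own. All 41 human probes passed the filter on dim probes. The ratios were fitted with lmFit and eBayes with the knockdown RNA as a block and a correlation of 0.5 between ratios 1 and 2, since 3 arrays do not allow an estimate. That value assumes that knockdown and control cultures vary equally and that arrays add no noise, which 3 ratios cannot check. Through the shared Cy3 measurement, ratios 1 and 2 also share any noise of that channel. Adjusted p-values are Benjamini-Hochberg values over the 41 probes, and a call is an adjusted p under 0.05. In the main fit limma pooled the variance fully (infinite prior degrees of freedom), so all 41 probes have the same SE of 0.13. It is not a probe's own spread, as SDs over the 3 ratios ran from 0.028 for Ala2h to 0.27 for Ser2h. After dye subtraction the prior degrees of freedom were 59.3. Such pooling treats probes as independent, which a shift common to an array does not meet. No correction for dye was made in the main estimates. Values with the dye control subtracted, an alternative also fixed before the data were examined, stand beside them. The standard errors of those values leave out the error of the single dye control array, which all 3 ratios then share.

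Lists of probes by amino acid were fixed before the data were examined, and 7 could be formed. They were tested with fry in the same fit and with cameraPR with a preset correlation of 0.01 and with an estimated one. Lists by anticodon, initiator tRNA and mitochondrial tRNAs could not be formed from the probe names, and the 2 methionine probes were left out of the lists. The shift of all human probes was tested with an exact two-sided sign-flip test of the 3 medians. Probes named in the text are those past the threshold, the 10 highest and 10 lowest log2 ratios, the selenocysteine probe and the 2 largest members of each list. Val1h falls outside this rule and was chosen after its values were seen. The number of tRNA genes per amino acid was counted in the RefSeq table of GRCh38.p14 by symbol. The sources used here name no build for the probes, so no coordinates are given.

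The fit was tested on simulated data with 41 probes, of which 10 changed, in 200 runs per size. Simulated ratios 1 and 2 shared a knockdown term as the fit assumes, all probes had equal noise, and none had a dye bias. With a shift common to all probes of an array, 38.9% of changes of 0.25 in log2, 96.8% of changes of 0.5 and 100% of changes of 1 were recovered, with 1.64, 2.09 and 1.31 unchanged probes called per run. Without such a shift 91.2%, 99.9% and 100% were recovered, with 0.39, 0.36 and 0.36 unchanged probes called per run.

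Alternatives fixed before the data were examined were other background corrections, other scales, each standard left out, the mean of the spots, flagged spots kept, other filters, other treatments of the shared knockdown RNA, the deposited ratios, the dye control subtracted and each ratio left out. Alternatives added after seeing the data combined dye subtraction with other choices, left out dim spots (under 50 units), took the ratio of channel medians or used median pixels. The number of arrays limits the precision. The mRNA of eIF3e is not measured by this array, so the knockdown itself was not checked here.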

Results

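tRNA abundance was measured on two-colour arrays as 3 ratios of eIF3e knockdown over control in MCF-10A cells, from 2 knockdown and 3 control cultures. Each ratio covered 41 human tRNA probes with 16 spots each and 4 spiked tRNA standards. The median spot intensity in Cy3, the knockdown channel, was 2875 in the Cy3 values that ratios 1 and 2 share and 2236 in ratio 3. In Atto635, the control channel, it was 1605, 1319 and 734. The labels leave open whether an abundance or a charging procedure was used, and the values are read here as abundance. The question was whether depletion of this initiation factor subunit changes the tRNA pool.

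The histidine tRNA probe His1h had the highest ratio on the array, 1.63-fold in knockdown over control (log2 0.71, SE 0.13, limma adjusted p = 3.64e-05, higher in 3 of 3 ratios). It was higher by 1.36-fold when the dye control was subtracted (log2 0.45, SE 0.12, adjusted p = 0.0191). The log2 ratios of His1h were 0.69, 0.81 and 0.65 in the 3 ratios, and 0.46, 0.57 and 0.36 with the dye control subtracted. In the RefSeq annotation all 9 nuclear histidine tRNA genes carry the anticodon GTG. Ile1h, Arg3h and Ser2h, probes for an isoleucine, an arginine and a serine tRNA, were also called higher, and Arg1h, another arginine probe, lower. None of these 4 passed when the dye control was subtracted with all other choices kept, while the authors' deposited ratios, which are divided by the dye control, called Ile1h, Arg3h and Ser2h higher in the same limma fit.

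Ile1h reached 1.37-fold (log2 0.46, SE 0.13, limma adjusted p = 0.0126), Arg3h 1.34-fold (0.42, SE 0.13, adjusted p = 0.0167) and Ser2h 1.34-fold (0.42, SE 0.13, adjusted p = 0.0167). Each was above 0 in all 3 ratios, from 0.37 to 0.52 for Ile1h, from 0.23 to 0.63 for Arg3h and from 0.08 to 0.60 for Ser2h. With the dye control subtracted the log2 ratio was 0.37 for Arg3h (SE 0.12, adjusted p = 0.0604), 0.27 for Ile1h (SE 0.12, adjusted p = 0.203) and 0.30 for Ser2h (SE 0.13, adjusted p = 0.203). Arg1h was at 0.726-fold (log2 -0.46, SE 0.13, adjusted p = 0.0126) and turned to 0.10 (SE 0.12, adjusted p = 0.841) with the dye control subtracted. Its value depended on the background correction too, at -0.08 without one (adjusted p = 0.701), -0.021 with plain subtraction (adjusted p = 0.926) and -0.035 with a normexp offset of 0 (adjusted p = 0.879). Its ratio on the dye control itself was -0.60, the lowest of the 41 probes, and it was also the dimmest probe, with a median Cy3 intensity of 100 on array 1 and 137.5 on array 3.

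**Figure D1:**
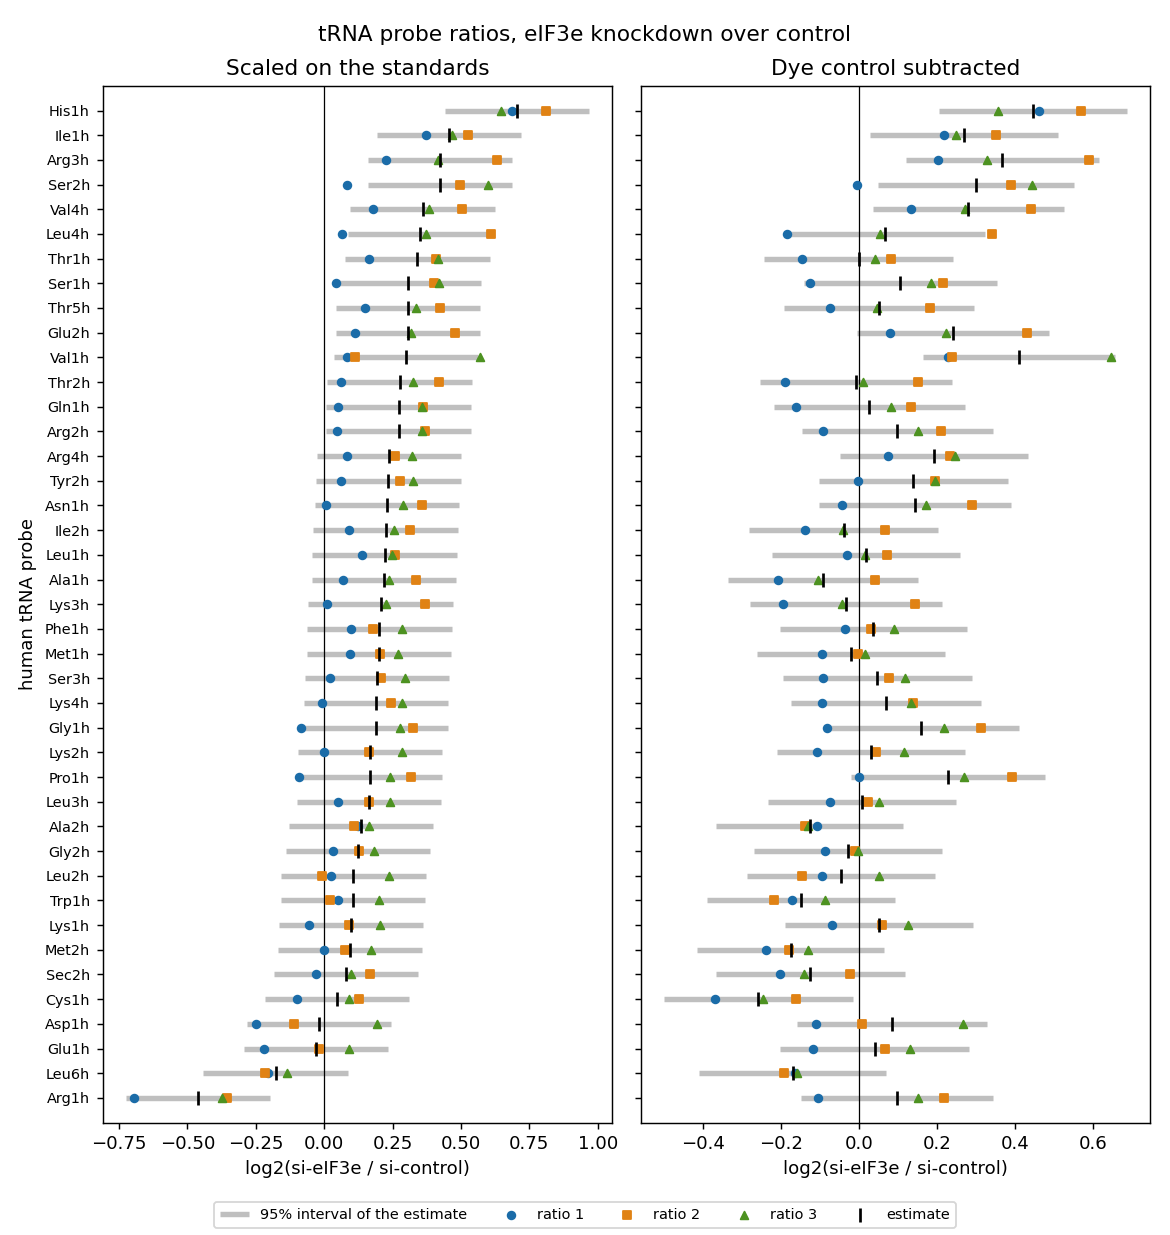
Log2 ratio of knockdown over control for each of the 41 human tRNA probes, scaled on the standards (left) and with the dye control subtracted (right). Points are the 3 ratios, black ticks the estimates and grey bars their 95% intervals; His1h has the highest estimate on both sides, though on the right Arg3h lies above it in ratio 2 (0.59 against 0.57) and Val1h (0.65) and Ser2h (0.44) above it in ratio 3 (0.36), and Arg1h, lowest on the left at -0.46, lies at 0.10 on the right.

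Val1h, a valine probe, was the other probe called with the dye control subtracted, at 1.33-fold (log2 0.41, SE 0.12, limma adjusted p = 0.0291, higher in 3 of 3 ratios). Scaled on the standards alone it was at 0.30 (SE 0.13, adjusted p = 0.0905). Its corrected ratios were 0.23, 0.24 and 0.65, and the highest came from ratio 3, which used the second knockdown RNA. The second valine probe, Val4h, had a corrected log2 ratio of 0.28 (SE 0.12, adjusted p = 0.203) and an uncorrected one of 0.36 (SE 0.13, adjusted p = 0.0555). In the authors' deposited ratios both Val1h and Val4h were called higher in the same limma fit. Val1h lost its call on the standards' scale when dim spots were left out of the corrected values (log2 0.41, adjusted p = 0.0557), an alternative chosen after seeing the data.

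In all, limma called 4 probes higher and 1 lower at an adjusted p under 0.05, and 15 of the 41 reached an unadjusted p under 0.05. After dye subtraction it called 2 higher and 0 lower, with 7 at an unadjusted p under 0.05. Centred on the median human probe in place of the standards, the same 4 were higher and 4 were lower (Arg1h, Asp1h, Glu1h and Leu6h), and with the dye control subtracted as well 3 were higher (His1h, Val1h and Arg3h) and 1 lower (Cys1h). Without ratio 3, the only one from the second knockdown RNA, 0 probes were called in either direction (2 at an unadjusted p under 0.05), without ratio 1 the counts were 31 and 2, and without ratio 2 they were 2 and 1. The ratios left without ratio 3 share 1 knockdown RNA and the Cy3 measurement, and their medians over the human probes were 0.05 and 0.26. Without ratio 1 the medians left were 0.26 and 0.28, so a shift common to all probes can add calls there. These counts therefore cannot show whether the calls depend on the second knockdown RNA. In simulated data with a shift common to an array, 1.31 to 2.09 unchanged probes were called per run, so a count of 5 can hold such probes. The simulated data held no dye bias of single probes, so calls from that source come on top.

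Over all human probes the median log2 ratio against the spiked standards was 0.05, 0.26 and 0.28 in the 3 ratios, a mean of 0.20 ± 0.13 (SD, n = 3, exact sign-flip test, two-sided p = 0.25, the smallest that 3 ratios allow). Dye subtraction gave medians of -0.09, 0.13 and 0.11, a mean of 0.05 ± 0.13 (SD, n = 3, exact p = 0.50). That test takes the ratios as independent; with ratios 1 and 2, which share a knockdown RNA and the Cy3 measurement, averaged, the mean was 0.22 (exact p = 0.50), so neither test can settle whether the whole pool shifted. The log2 ratios of the single standards had SDs of 0.20, 0.17 and 0.21. Leaving out each standard in turn gave a mean shift between 0.18 and 0.21. That range had to be narrow, since E.c. Lys-2 and E.c. Tyr-2 lay within 0.026 of the standards' median in each ratio. E.c. Ala-5 was at -0.17, -0.07 and -0.04 and Yeast Phe-3 at 0.31, 0.31 and 0.40, so the range does not measure the error of the scale. A total of 37 probes had estimates above 0, and 29 were above 0 in all 3 ratios, against 2 below 0 in all 3. After dye subtraction 27 estimates were above 0, and 8 probes were above and 7 below 0 in all 3 ratios.

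The lists fixed by amino acid did not pass either list test. The 14 aliphatic probes, for small and hydrophobic amino acids, averaged 0.20 in log2 (fry adjusted p = 0.278), with Ile1h called higher and Val4h (0.36) and Leu4h (0.35, adjusted p = 0.0558) below the threshold. Adjusted over the list alone, 3 aliphatic probes passed. Leu6h, another aliphatic probe, was at -0.18 (SE 0.13, adjusted p = 0.269) and lay below 0 in 3 of 3 ratios both before and after dye subtraction (-0.17, adjusted p = 0.545). It was called lower, at -0.39, centred on the median human probe (adjusted p = 5.48e-05) and with loess (adjusted p = 0.0103). With the dye control subtracted and median centring together, Leu6h was at -0.23 (SE 0.08, limma adjusted p = 0.0775) and not called. The 13 probes for amino acids common in membrane-spanning segments averaged 0.21 (fry adjusted p = 0.276), with 1 called higher over all probes and 3 when adjusted over the list alone. After dye subtraction these averages were 0.07 and 0.04, each with a fry adjusted p of 0.876.

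The 9 basic probes, which carry lysine, arginine or histidine, averaged 0.20 (fry adjusted p = 0.278), with His1h and Arg3h called higher and Arg1h lower. Adjusted over the list alone the counts were the same, 2 and 1. They averaged 0.15 after dye subtraction (fry adjusted p = 0.876), with 1 called higher over all probes and 2 over the list alone. Lys1h was at 0.10 (adjusted p = 0.526). The 3 acidic probes, for aspartate and glutamate, averaged 0.09 (fry adjusted p = 0.577) with a median of -0.02. Glu2h was at 0.31 (adjusted p = 0.0881), Glu1h at -0.03 (adjusted p = 0.846) and Asp1h at -0.02 (adjusted p = 0.884), the last pair at 0.04 and 0.08 after dye subtraction, and none was called over all probes or over the list alone. Their average was 0.12 with the dye control subtracted (fry adjusted p = 0.876).

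The 9 polar uncharged probes averaged 0.27 (fry adjusted p = 0.278), the second highest list average, with Ser2h called higher over all probes and over the list alone. Thr1h (0.34, adjusted p = 0.0610), Ser1h (0.31, adjusted p = 0.0881) and Thr5h (0.31, adjusted p = 0.0881) did not pass, and after dye subtraction they were at -0.0014, 0.11 and 0.05. Cys1h was at 0.05 (SE 0.13, adjusted p = 0.760) and at -0.26 with the dye control subtracted (SE 0.12, adjusted p = 0.216). With the dye control subtracted and the human probes centred on their median it was called lower, at 0.802-fold (log2 -0.32, SE 0.06, limma adjusted p = 0.0124). The list average was 0.04 with the dye control subtracted (fry adjusted p = 0.885). The 3 aromatic probes averaged 0.18 (fry adjusted p = 0.276) and 0.01 with the dye control subtracted (fry adjusted p = 0.885), with Tyr2h at 0.23 (adjusted p = 0.194), Phe1h at 0.20 (adjusted p = 0.228) and Trp1h at 0.11 (adjusted p = 0.499), which turned to -0.15 after dye subtraction. None of the 3 passed over the list alone.

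Queuosine is a modified base at the first anticodon position of the tRNAs for histidine, asparagine, aspartate and tyrosine. The 4 probes for these amino acids had the highest list average, 0.29 (fry adjusted p = 0.276), and 0.20 with the dye control subtracted (fry adjusted p = 0.876). His1h was the only member called, over all probes and over the list alone. Tyr2h (0.23) lay close to the median probe, and Asp1h was at -0.02. Centred on the median human probe without dye subtraction the list averaged 0.08 and passed fry (adjusted p = 0.00274) but not camera (adjusted p = 0.937, and adjusted p = 0.980 with an estimated correlation). There His1h was at 0.49, Tyr2h at 0.02 and Asp1h at -0.23 and called lower (adjusted p = 0.0184). Dye subtraction and median centring together gave a list average of 0.14 (fry adjusted p = 0.0905). On the standards' scale the camera test with its preset correlation gave adjusted p-values of 0.872 to 0.995 over the 7 lists and of 0.998 for each with an estimated correlation. With the dye control subtracted these were 0.339 to 0.986 and 0.924 to 0.992.

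The selenocysteine probe Sec2h, for the tRNA that inserts selenocysteine at UGA codons, was at 0.08 (SE 0.13, limma adjusted p = 0.587), and at -0.13 (SE 0.12, adjusted p = 0.693) with the dye control subtracted. Met2h, a methionine probe, was at 0.10 (SE 0.13, adjusted p = 0.526) and at -0.18 (SE 0.12, adjusted p = 0.545) after that subtraction. Whether Met1h or Met2h reads the initiator tRNA is not given by the probe names. Leu2h was at 0.11 (adjusted p = 0.499) and at -0.05 (adjusted p = 0.949) after subtraction.

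Across the 41 probes, which are not independent replicates, the 3 ratios correlated with each other with r from 0.791 to 0.816 and with the dye control subtracted with r from 0.717 to 0.773. Ratios 1 and 3, which share no culture, correlated at 0.816 and 0.773. By rank (Spearman's rho) the values ran from 0.631 to 0.800 uncorrected and from 0.638 to 0.801 with the dye control subtracted. For ratios 1 and 3 they were 0.666 and 0.782. With no dyes swapped, uncorrected ratios also share any dye bias of a probe, so their correlation need not come from the cultures. Subtraction of 1 common dye control adds a shared term to the corrected values. Within probes, the spots' deviations in both channels correlated at 0.969 in ratio 1 and 0.961 in ratio 3, and at 0.254 in ratio 2.

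**Figure D2:**
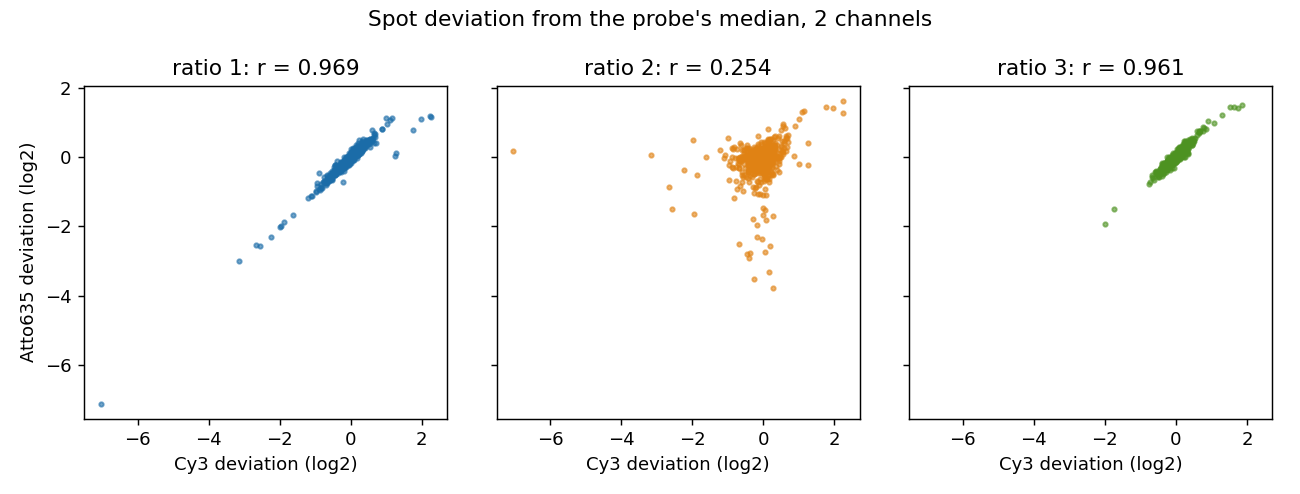
Deviation of each spot from its probe's median in log2, Cy3 on the x axis and Atto635 on the y axis, for human probe spots in the 3 ratios. The channels follow each other spot by spot in ratios 1 (r = 0.969) and 3 (r = 0.961) and much less in ratio 2 (r = 0.254).

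**Figure D3:**
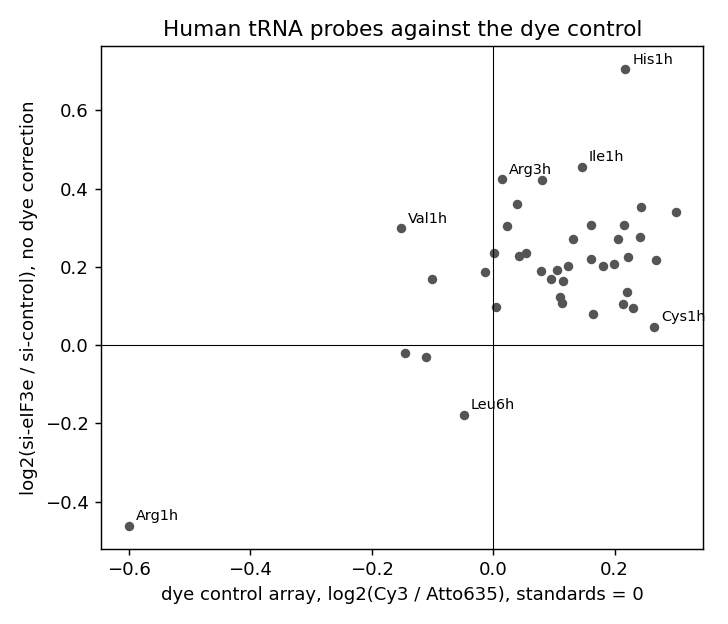
Log2 ratio of each of the 41 human probes on the dye control array (x axis, standards at 0) against its uncorrected log2 ratio of knockdown over control (y axis); each point is a probe. Arg1h is lowest on both axes, at -0.60 and -0.46, and His1h is highest on the y axis at 0.71.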

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

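The tests of dye bias, of aberrant spots and of stray signal at spot edges were chosen after the values they measure had been seen. The tests of spot noise on the dye control and of swapped dyes were set out before.

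The dye control array, which enters no comparison of the main estimates, showed ratios that differ between human probes, with an SD of 0.161 in log2, close to the SD of 0.182 of the uncorrected knockdown ratios. Across the 41 probes, which are not independent replicates, the uncorrected ratios correlated with those of the dye control at r = 0.569 (permutation p = 0.00101), which is consistent with a dye bias of single probes in part of the spread. Much of this rests on Arg1h and Val1h: without these 2 probes r was 0.341 (permutation p = 0.0330), and Spearman's rho over all probes was 0.231 (permutation p = 0.143). Arg1h is the dimmest probe, and its low uncorrected ratio depended on the background correction. Both sets of ratios used the same normexp offset, so for Arg1h a dye bias cannot be told apart from an effect of that offset. Spot noise of the dye control was too small to account for the spread that remains after subtraction, since its variance was 0.0686 of the covariance of corrected ratios 1 and 3 (upper bootstrap bound 0.212). Other errors of this single array are shared by all corrected ratios and stay open, as does a knockdown effect.

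His1h lay above the other human probes in all 3 uncorrected ratios, and after dye subtraction in ratio 1 but below Arg3h in ratio 2 (0.57 against 0.59) and below Val1h and Ser2h in ratio 3 (0.36 against 0.65 and 0.44). Dye bias as the dye control measures it was not enough to account for its excess over the median probe, with a log2 ratio of 0.387 left after dye subtraction and median centring (limma adjusted p = 0.0124). All 16 spots on array 1 and all 14 unflagged spots on array 3, 100%, lay above the median human probe. His1h stood out by the median of these same spots, so many of them had to lie above it. Only the full share adds that the excess did not rest on a few aberrant spots. Median pixels gave 1.01 times the excess of mean pixels, which argues against stray signal at spot edges. Dye behaviour that differed between the dye control and the other arrays cannot be told apart from a higher level of tRNA-His after eIF3e knockdown, since 0 arrays had the dyes swapped, and both stay open. The call ended without ratio 3, where its log2 ratio was 0.75 (adjusted p = 0.0735), and 0.50 (adjusted p = 0.356) with dye subtraction and median centring.

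Spots printed with water alone carried signal: their median Cy3 intensity was 4207.5 on array 1, 11207 on array 3 and 5925 on the dye control, brighter than 26, 40 and 33 of the 41 human probes, while by median pixels it was 33 on array 1 and 290 on array 3.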

How the results depend on the processing

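Settings that combine dye subtraction with another choice, and those on dim spots, channel medians and median pixels, were chosen after seeing the data. Against 4 probes higher and 1 lower, the counts were 2 and 0 without background correction, 5 and 0 with plain subtraction and 7 and 0 with an offset of 0. They were 4 and 4 centred on the median human probe, 1 and 1 with loess (His1h and Leu6h, with Arg1h at -0.15, adjusted p = 0.152), 40 and 0 without scaling, 11 and 1 without E.c. Lys-2 in the scale and 10 and 1 without Yeast Phe-3. The mean of the spots gave 1 and 0, the ratios taken as independent 20 and 1, ratios 1 and 2 averaged 28 and 1, and the deposited ratios 6 and 0. With the dye control subtracted the counts were 2 and 0, with median centring as well 3 and 1, without E.c. Lys-2 3 and 0, with the ratios as independent 8 and 1, with plain subtraction and without E.c. Lys-2 1 and 0, and without dim spots 1 and 0. Leaving out dim spots alone gave 4 and 0, and median pixels of ratios 1 and 3 gave 1 and 1. Leaving out 1 ratio, with or without dye subtraction and median centring, gave 0 to 31 higher and 0 to 7 lower, and 0 in both directions whenever ratio 3, the only one from the second knockdown RNA, was left out, and also without ratio 1 when the dye control was subtracted on the standards' scale (8 and 7 with median centring as well). His1h kept its sign in 36 of 36 settings, the main one included, and was called in 32 (limma adjusted p from 5.86e-12 to 0.812); the exceptions left out ratio 3, or ratio 1 with the dye control subtracted on the standards' scale. Ile1h, Arg3h and Ser2h also kept their sign in all 36 and were called in 23, 23 and 20, and in 4, 6 and 4 of the 13 settings with dye subtraction or the deposited ratios. Both the deposited ratios and dye subtraction with independent ratios called all 3. Leu6h was called in 6, with both signs among them. Arg1h kept its sign in 23 and was called in 15, none of them with dye subtraction or the deposited ratios; with dye subtraction and without dim spots it was at -0.31 (adjusted p = 0.216). Both alternative filters removed no probe, so they tested nothing, and in these tallies they repeat the main fit. The tallies also hold the setting without scaling, where 40 of the 41 probes were called higher. A call or a positive sign there sets no probe apart. The setting without background correction still used subtracted Atto635 values for ratio 2, since no others fit that ratio. The median shift stayed above 0 in every setting where it is not 0 by construction, and its test cannot pass with 3 ratios. Its size varied widely, from 0.0072 with loess, which itself removes most of a common shift, to 1.11 without scaling, which keeps any difference between channels. It was 0.10 in the deposited ratios and 0.010 with dye subtraction and without ratio 2. The sign alone is thus weak evidence of a shift. Signal over background limits Arg1h most, the dimmest probe, and a change of the normexp offset alone removed its call. Beyond this and the smaller number of ratios left, the cause of the changes was not tested.

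Among the lists and the probes named in the text, the log2 values that changed sign were of those not called in the main estimates, except Arg1h. Other probes, Met1h among them, are not listed here, and some of these changed sign too. Centred on the median human probe these were the aliphatic list (-0.0077), the aromatic list (-0.030), the basic list (-0.0062), the acidic list (-0.12), the membrane-segment list (-0.0053), Cys1h (-0.16), Leu2h (-0.10), Lys1h (-0.11), Met2h (-0.12), Phe1h (-0.0087), Sec2h (-0.13) and Trp1h (-0.10), and the queuosine list (0.077) passed its test. With loess they were the aromatic list (-0.042), Cys1h (-0.14), Leu2h (-0.11), Met2h (-0.16), Sec2h (-0.067), Trp1h (-0.11) and Tyr2h (-0.056). Without scaling they were Arg1h (0.49), Asp1h (0.93), Glu1h (0.92) and Leu6h (0.77). Asp1h turned with ratios 1 and 2 averaged (0.0073) and with channel medians (0.028). In the deposited ratios they were Arg1h (0.23), Asp1h (0.18), Cys1h (-0.23), Glu1h (0.086), Leu2h (-0.032), Met2h (-0.12) and Trp1h (-0.092). With the dye control subtracted they were Arg1h (0.10), Asp1h (0.084), Cys1h (-0.26), Glu1h (0.040), Leu2h (-0.047), Met2h (-0.18), Sec2h (-0.13), Thr1h (-0.0014) and Trp1h (-0.15). With median centring as well they were the aromatic list (-0.051), the polar list (-0.015), the membrane-segment list (-0.024), Arg1h (0.037), Asp1h (0.024), Cys1h (-0.32), Leu2h (-0.11), Lys1h (-0.0087), Met2h (-0.24), Phe1h (-0.024), Sec2h (-0.19), Thr1h (-0.061), Thr5h (-0.0096) and Trp1h (-0.21). With dye subtraction and without E.c. Lys-2 they were Arg1h (0.12), Asp1h (0.11), Cys1h (-0.23), Glu1h (0.065), Leu2h (-0.023), Met2h (-0.15), Sec2h (-0.10) and Trp1h (-0.12). With dye subtraction and independent ratios they were the aromatic list (-0.00082), Arg1h (0.088), Asp1h (0.054), Cys1h (-0.26), Glu1h (0.026), Leu2h (-0.064), Met2h (-0.18), Sec2h (-0.12), Thr1h (-0.0084) and Trp1h (-0.16). With dye subtraction, plain background subtraction and no E.c. Lys-2 they were Arg1h (0.24), Asp1h (0.12), Cys1h (-0.25), Glu1h (0.069), Leu2h (-0.024), Met2h (-0.14), Sec2h (-0.11) and Trp1h (-0.12). With dye subtraction and without dim spots they were Asp1h (0.098), Cys1h (-0.26), Glu1h (0.040), Leu2h (-0.047), Met2h (-0.18), Sec2h (-0.13), Thr1h (-0.0014) and Trp1h (-0.15). With 1 ratio left out, list averages ran from -0.010 to 0.26 for the aliphatic list, -0.090 to 0.21 for the aromatic list, 0.081 to 0.28 for the basic list, -0.0013 to 0.19 for the acidic list, -0.054 to 0.25 for the membrane-segment list, -0.030 to 0.35 for the polar list and 0.13 to 0.35 for the queuosine list. Without ratio 1 the aliphatic, polar, basic and queuosine lists passed fry (adjusted p = 0.0483 each), and with dye subtraction and median centring the queuosine list did (adjusted p = 0.00423). None of these passed camera with its preset correlation (adjusted p from 0.843 to 0.964, and 0.395 for the last), and an estimated correlation gave no value with 2 ratios. The queuosine list centred on the median human probe did not pass camera (adjusted p = 0.937, and adjusted p = 0.980 with an estimated correlation). Probes ran from -0.54 to 0.18 for Arg1h, -0.18 to 0.14 for Asp1h, -0.33 to 0.11 for Cys1h, -0.12 to 0.10 for Glu1h, -0.17 to 0.13 for Leu2h, -0.076 to 0.49 for Leu4h, -0.031 to 0.15 for Lys1h, -0.28 to 0.12 for Met2h, -0.064 to 0.23 for Phe1h, -0.21 to 0.13 for Sec2h, -0.063 to 0.41 for Thr1h, -0.025 to 0.38 for Thr5h and -0.28 to 0.12 for Trp1h.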

Other observations

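The test on isoacceptor probes was set out before its result, and both tests on the table of ratio 2 were chosen after the values had been seen.

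Several amino acids are read by more than 1 probe, and the hypothesis was tested that probes of 1 amino acid move together. With the dye control subtracted and the human probes centred on their median, the SD within amino acids was 0.108 in log2 over 31 probes of 11 amino acids, against a median of 0.149 after random relabelling (one-sided permutation p = 0.00728). The 2 alanine probes lay within 0.035 of each other and the 3 threonine probes within 0.058, while the 2 isoleucine probes were 0.31 apart and the 4 arginine probes spanned 0.27. Without dye subtraction the p was 0.825. It was 0.108 for the dye control's own ratios, 0.0571 for corrected ratio 1 and 0.00440 for corrected ratio 3. Among the uncorrected values the arginine probes lay far apart, at -0.46 (Arg1h), 0.27, 0.42 and 0.24. Arg1h is the dimmest probe, and its uncorrected value depended on the background correction. Whether the result depends on dye subtraction beyond this probe was not tested. Probes of 1 amino acid may also cross-hybridise, which these data do not separate from shared regulation. Corrected ratios 1 and 3 are not independent support, since both carry the error of the single dye control array, which stays open as a source too.

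The table of ratio 2 repeats that of ratio 1 in all columns but the background-subtracted Atto635 intensity, and spots of a probe that are bright in one channel were only weakly bright in the other (r = 0.254, against over 0.96 in the other ratios). This is consistent with an Atto635 column from another slide than the Cy3 column. A reordered copy of array 1 is argued against, since only 0.50% of the sorted values were equal. No biological explanation was tested for this pattern. Ratio 2 would then lose the cancellation of spot differences within a slide, and the median over 16 spots is what limits that noise.

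Val1h had 4 of its 16 spots under 50 units at the same positions on all 3 slides, in 2 blocks. Its remaining spots had a median Cy3 intensity of 7636.5 on array 1, 8832 on array 3 and 15128 on the dye control. Without dim spots its dye-subtracted, median-centred log2 ratio was 0.38 (SE 0.08, limma adjusted p = 0.0317).

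The standard E.c. Lys-2, absent from the deposited ratios, lay within 0.026 of the standards' median in each uncorrected ratio and at 0.37, 0.32 and 0.27 with the dye control subtracted. One standard is named E.c. Ala-5 in the scanner tables and described as a yeast tRNA in the labels.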
